A study of Homo sapiens with 33 samples.

How the data were processed

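RNA was measured in 33 libraries of cells labelled Huh7, a human line derived from a hepatocellular carcinoma. Per the labels' protocols, cells were infected with lentivirus made in HEK293T cells, with 4 µg/mL polybrene, and put under puromycin from 24 h after infection. RNA was taken at days 2, 4 and 6. The genotypes were a control, a knockout of CDK16, a knockout of CDK18, and a double knockout of both, written CDK16/18 dKO. Each of the 12 groups held 3 libraries, apart from CDK18 KO, with 2 at each day. Libraries were made from 250 ng of total RNA, with a mean RNA integrity number of 8.8 and a range of 5.0 to 9.8, using QuantSeq 3′ mRNA-Seq in the forward orientation, per the labels' protocols. That kit primes on the poly(A) tail and gives 1 sense-strand read near the 3′ end of each transcript. A small deletion or insertion elsewhere in a gene leaves such a tag in place, so the counts of CDK16 and CDK18 show the level of their transcripts and cannot show whether the protein was lost.

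The deposited values are whole-number counts per gene, not normalized, 1 file for each library, as the authors made them. Per the submitters' processing notes, TopHat2 2.0.10, TopHat, Bowtie2 2.0.10, SAMtools 0.1.19, HTSeq and DESeq2 were used with GRCh38/hg38; the notes give no order of steps, and the annotation release is not given in the sources used here. Whether the counting used the strand is not given either. Each file held 60204 lines: 60107 gene identifiers, 92 spike-in sequences and 5 tally lines of the counting tool. The spike-ins held 24 counts over all libraries, at most 3 in a library, and were left out. The tally lines were left out of library sizes and tests. Reads outside any gene made up 6.98% to 14.1% of all tallied reads, reads in more than 1 gene 0.692% to 0.928%, and reads with more than 1 alignment 34.7% to 51.2%. Counts in genes made up the other 40.6% to 53.4%. The share with more than 1 alignment means that genes with near-identical copies, ribosomal protein genes among them, were counted from part of their reads. Symbols were matched for 56104 identifiers and positions for 56531, the latter from GENCODE release 29, on GRCh38.

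Gene counts totalled 7.62 M to 13.1 M per library (median 9.58 M), and 20400 to 22561 genes had at least 1 count. Levels are in CPM, counts for each M gene counts, so 1 CPM is 7.62 to 13.1 reads and levels near it are imprecise. These reads carry no molecular identifiers used here, so counting error is a lower limit of their error. Mitochondrially encoded genes held 8.06% to 11.7% of gene counts. No pair of libraries of a group was identical in 30 pairs compared, and each pair differed by more than sampling noise (chi-square per degree of freedom 2.16 to 46.3, over genes with at least 10 counts). The labels do not say whether replicates were separate infections, so p-values measure the spread between these libraries, which may be technical.

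Counts were tested with edgeR 4.0.16 in R 4.3.3: the quasi-likelihood test with robust estimation, TMM normalization (scaling factors 0.955 to 1.04) and edgeR's expression filter on the 12 groups (minimum count 10, minimum total 15), which kept 16103 genes. A model with 1 coefficient for each of the 12 groups used all 33 libraries and left 21 residual degrees of freedom. The common biological coefficient of variation was 0.160. Adjusted p-values are Benjamini-Hochberg values within a comparison, with 0.05 as the threshold, and a gene past it is called. Comparisons were each knockout against control on each day, the mean over the 3 days of those differences, the double against each single knockout, the change of each knockout's effect from day 2 to day 6 (an interaction), and control at day 6 against day 2. Log2 fold changes carry the fitted standard error (SE); levels are TMM-scaled CPM with the SD over libraries.

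The design, these 18 comparisons, the alternatives other than those named as added, and 30 gene lists were fixed before the data were examined. The 30 lists cover the CDK16 family with its cyclins (TAIRE kinases and cyclin Y), nucleoporins, nuclear transport factors, homologous recombination, the Fanconi anaemia pathway, end joining, excision and mismatch repair, DNA damage signalling, p53 target genes, G1/S and replication genes, G2/M genes, hepatocyte plasma proteins, hepatocyte transcription factors, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia genes, the ATF4 response, the unfolded protein response, the heat shock response, interferon-stimulated genes, NF-kB and acute-phase genes, YAP/TEAD target genes, mesenchymal and adhesion genes, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, ribosomal proteins, autophagy and lysosome genes, and markers of HEK293T-like, fibroblast-like and blood cells. Of 886 list entries, 1 had no matching identifier. Lists were tested with camera (limma 3.58.1) on voom values at a preset inter-gene correlation of 0.01, and again with a correlation estimated for each list; fry was run beside it. List p-values were adjusted over the 30 lists, and over the lists of all 3 comparisons together for the mean of days.

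Genes named in the text followed a rule. CDK16, CDK18 and their family are always given. For a mean-of-days comparison with control the rule takes up to 10 called genes in each direction by size of fold change, with at least 5 CPM on average and 1 sign at all days. For other comparisons it takes up to 3 in each direction, with the libraries of both groups fully apart. Where no gene passed, the 3 with the smallest p are given. For a list it takes up to 4 members with the smallest p. A gene named outside the rule is said to be chosen after its values were seen.

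The alternatives fixed in advance were size factors of the RLE type, no expression filter, the replicate number as a block, a fit on the compared groups alone, limma with library quality weights, DESeq2 1.42.0, an estimated correlation for lists, and leaving out each of the 33 libraries in turn. Added after the data were examined were a fit without the control libraries numbered 3 at days 4 and 6, on 31 libraries, and a pair of time comparisons over the knockout genotypes alone. The correlation of fold changes between knockouts was set beside 20 simulations of unchanged groups against the same controls. The scripts were tested on simulated counts of the 16103 genes. For CDK16 KO against control at day 4, 14.9% of genes changed 1.5-fold, 50.7% of genes changed 2-fold and 78.8% of genes changed 4-fold were recovered; for the mean of days the shares were 47.8%, 82.1% and 95.5%. For the change of the double knockout's effect with time they were 2.99%, 28.4% and 74.2%. In each simulation 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold, all at once. Many changed genes ease the adjusted threshold, so these shares can overstate the recovery where few genes change.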

Results

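Cells labelled Huh7 were profiled at days 2, 4 and 6 after infection, as control (9 libraries), CDK16 KO (9), CDK18 KO (6) and CDK16/18 dKO (9). CDK16 and CDK18 are cyclin-dependent kinases of the PCTAIRE group, and CDK16 is activated by cyclin Y. The title of the series concerns repair of DNA at nuclear pores and liver cancer, so nucleoporin and DNA repair genes were among the groups examined. Depth was 7.62 M to 13.1 M gene counts per library.

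The targeted genes were examined first. CDK16 (ENSG00000102225, chromosome X, 47217860 to 47229997) stood at 144 ± 10.5 CPM in control cells at day 2 (SD, n = 3), 138 ± 27.7 at day 4 and 131 ± 15.98 at day 6. In CDK16 KO it stood at 106 ± 13.7, 62.4 ± 7.26 and 58.8 ± 16.2 CPM (n = 3 each). In CDK16/18 dKO it stood at 111 ± 5.43, 83.3 ± 11.1 and 55.6 ± 9.88 CPM (n = 3 each). Over the mean of days CDK16 fell by 0.91 on the log2 scale in CDK16 KO (SE 0.11, adjusted p = 2.70e-05) and by 0.78 in CDK16/18 dKO (SE 0.11, adjusted p = 7.18e-04). In CDK18 KO its log2 fold change was -0.22 (SE 0.12, adjusted p = 0.615). The CDK18 KO libraries held 115 and 70.9 CPM of CDK16 at day 2, 124 and 106 at day 4, and 186 and 121 at day 6. At day 2 they overlapped the CDK16 KO libraries, which held 91.3 to 118 CPM, so that day did not set the CDK16-targeted groups apart.

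CDK18 (ENSG00000117266, chromosome 1, 205504595 to 205532793) was a low-abundance transcript, at 7.23 ± 2.41 CPM in control (n = 9), 5.64 ± 2.57 in CDK18 KO (n = 6) and 5.37 ± 1.92 in CDK16/18 dKO (n = 9). Its mean-of-days log2 fold change was -0.45 in CDK18 KO (SE 0.21, adjusted p = 0.594) and -0.48 in CDK16/18 dKO (SE 0.18, adjusted p = 0.713), neither past the threshold. The transcript level therefore gave no check of the CDK18 KO label, and a 3′ tag cannot show a small edit. In knockout libraries CDK18 rose from day 2 to day 6 (log2 fold change 0.78, SE 0.19, adjusted p = 0.0015), a comparison added after the data were examined.

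**Figure D1:**
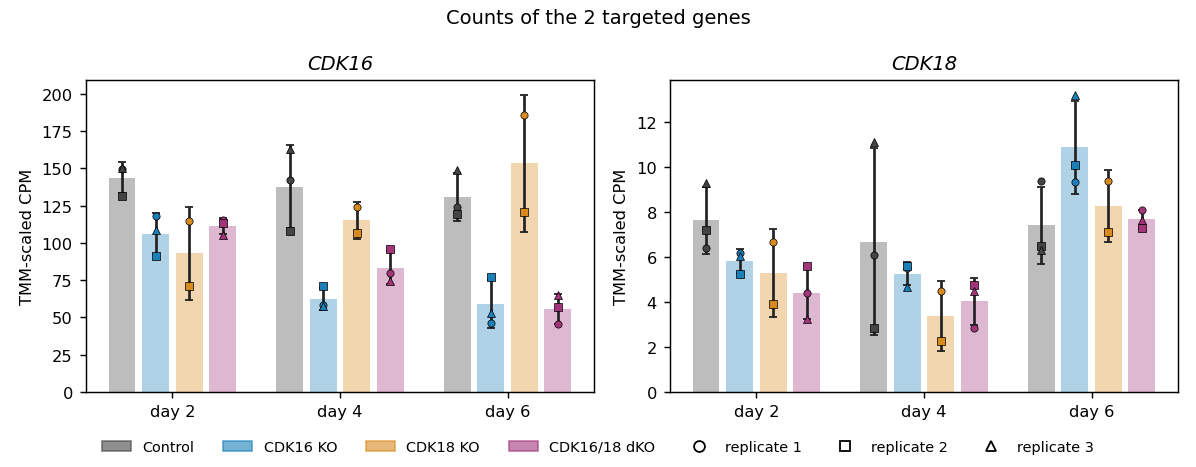
TMM-scaled CPM of CDK16 (left) and CDK18 (right) by labelled day and genotype. Bars are group means, error bars are the SD, and symbols are single libraries by replicate number. CDK16 in the CDK16-targeted groups stood at 58.8 and 55.6 CPM at day 6 against 131 in control, while CDK18 reached at most 13.2 CPM in a library.

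The other family members did not pass the threshold in any mean-of-days comparison with control. In CDK16/18 dKO, CDK14 had a log2 fold change of -0.05 (SE 0.10), CDK17 0.19 (SE 0.16), CCNY, the gene of cyclin Y, 0.02 (SE 0.07) and CCNYL1 -0.16 (SE 0.09). CDK15, at 0.502 CPM on average, had -0.13 (SE 0.63). The list of TAIRE kinases and cyclin Y was lower as a group in CDK16/18 dKO (median -0.13, adjusted p = 0.0388; adjusted p = 0.463 with an estimated correlation), with 1 of 7 members called over all genes and 2 adjusted over the list alone. Both of those 2 were the targets, CDK16 and CDK18.

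The day labels of the control libraries were examined next, after their values were seen. On an axis of 922 genes that differed at least 1 on the log2 scale between the knockout means of day 4 (place 0) and day 6 (place 1), the library labelled control day 4 replicate 3 stood at 0.996. The library labelled control day 6 replicate 3 stood at 0.027. The other control libraries stood at -0.029 to 0.015 at day 4 and 0.920 to 0.930 at day 6. Each knockout library was placed on a like axis, with genes and means taken from the other knockout genotypes alone. Both doubted libraries were kept as labelled, and they enter every value below unless it is given as without them.

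**Figure D2:**
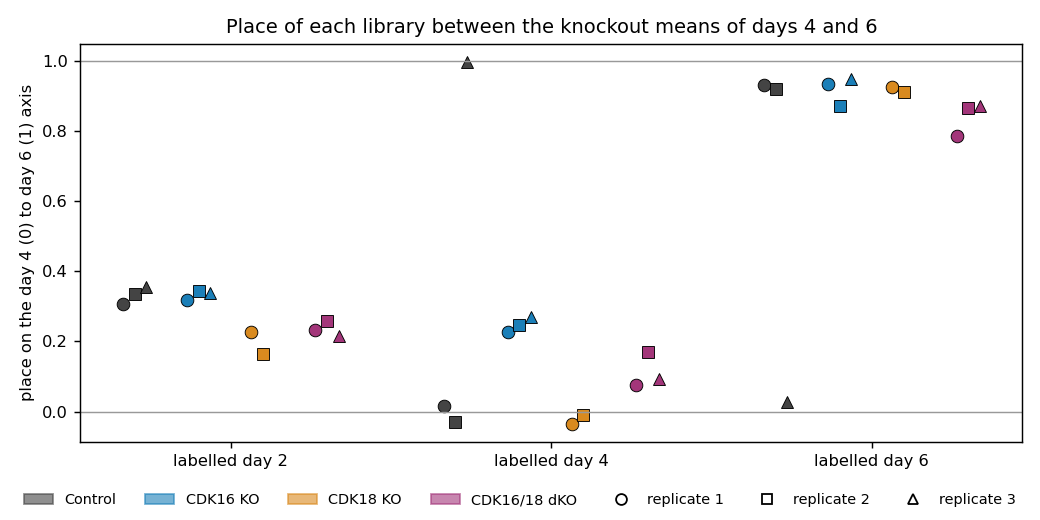
Place of each library of days 4 and 6 on an axis from the mean of the knockout libraries of day 4 (0) to that of day 6 (1), over 922 genes; each point is a library, by labelled day and genotype. The controls numbered 3 stand at 0.996 under the day 4 label and at 0.027 under the day 6 label.

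The first comparison asked what the loss of CDK16 did at each day. At day 4, 10 genes passed the threshold in CDK16 KO, 3 higher and 7 lower. DESeq2 called 36 and limma with quality weights 98, and a fit on the compared groups alone called 0, with ACKR3 at adjusted p = 0.390 and CDK16 at 0.743. SMAD6, an inhibitor of BMP signalling, rose to 19.8 ± 2.20 CPM from 10.7 ± 1.06 (log2 fold change 0.89, SE 0.17, adjusted p = 0.0161, n = 3 each), and TGFB2, a growth factor, rose by 0.80 (SE 0.14, adjusted p = 0.0125). IL24, a cytokine, fell by 0.97 on the log2 scale (SE 0.15, adjusted p = 0.0018), SOX9, a transcription factor, fell by 0.85 (SE 0.16, adjusted p = 0.0136), and CDK16 fell by 1.14 (SE 0.19, adjusted p = 0.0058). ACKR3, a chemokine scavenger receptor, chosen after its values were seen, rose from 0.718 ± 0.0693 to 4.35 ± 0.466 CPM (log2 fold change 2.59, SE 0.36, adjusted p = 4.89e-04). With both doubted controls left out 67 genes passed, 28 higher and 39 lower, 8 of them among the 10. Without control day 4 replicate 2 the count was 1113, and without control day 6 replicate 3 it was 17. It was 6 without control day 4 replicate 1, and 4 and 2 without CDK16 KO day 4 replicates 2 and 3.

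The fixed list of 22 heat shock genes had a median of 0.01 at day 4 in CDK16 KO (adjusted p = 0.474), with 0 called over all genes and 1 adjusted over the list alone. Without the doubted controls its median was -0.14 (adjusted p = 7.56e-04 with an estimated correlation), with 4 called over all genes and 4 adjusted over the list alone, while members such as HSPA4 and CHORDC1 had positive fold changes of 0.07 and 0.10. The CDK16 KO libraries of day 4 stood at 0.228 to 0.270 on a day axis from the other knockouts. The controls kept stood at 0.015 and -0.029 on the axis of all knockouts, which has other genes and another scale. Control libraries of day 2 stood at 0.307 to 0.356 there, so the place of the CDK16 KO libraries does not say toward which day. Genes that move with time, HSPA1A and LBH among them, can therefore differ with that place, and it was not separated from the genotype. The genes that follow were chosen after their values were seen, and their values are without those controls. HSPA1A, an inducible HSP70 whose reads may be shared with HSPA1B, had a log2 fold change of -1.02 (adjusted p = 0.0017), HSPA6 -2.86 (adjusted p = 6.19e-04), DNAJB1, an HSP40 co-chaperone, -0.63 (adjusted p = 0.0092) and BAG3 -0.76 (adjusted p = 0.0046). With all libraries none of these 4 passed, at adjusted p of 0.777, 0.310, 0.129 and 0.713. LBH, a transcription cofactor, rose by 1.94 on the log2 scale without those controls (adjusted p = 1.57e-05) and had 0.53 with them (adjusted p = 0.694).

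At day 6, 3 genes passed in CDK16 KO, and 6 with DESeq2, 5 with limma and quality weights and 0 with a fit on the compared groups alone. Leaving out control day 6 replicate 1 or 3, or CDK16 KO day 6 replicate 1 or 3, gave 0, and leaving out control day 4 replicate 3 gave 7. The L1CAM and RPL13AP20 calls were lost in 11 and 13 of 40 alternatives. L1CAM, a cell adhesion molecule, rose to 14.3 ± 1.65 CPM from 4.92 ± 1.61 (log2 fold change 1.53, SE 0.28, adjusted p = 0.0348), RPL13AP20, a ribosomal protein pseudogene whose reads may be shared with RPL13A, fell by 0.80 (SE 0.15, adjusted p = 0.0348), and CDK16 fell by 1.15 (SE 0.19, adjusted p = 0.0152). Without the doubted controls 3 passed, L1CAM, RPL13AP20 and ARHGDIB, the last at -1.11 (adjusted p = 0.0021, against 0.582 with all libraries), and CDK16 had an adjusted p of 0.112 at a log2 fold change of -1.04. At day 2 no gene passed with edgeR; 278 had an unadjusted p under 0.05, and DESeq2 and limma with quality weights called 0. The smallest p at day 2 belonged to THORLNC (log2 fold change -1.71), SEMA5A (1.57) and PIGX (-0.42), none past the threshold.

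Averaged over days, CDK16 and ACKR3 passed in CDK16 KO, the latter at 1.04 (SE 0.18, adjusted p = 0.0243). The ACKR3 call was lost in 15 of 40 alternatives, limma with quality weights among them. ACKR3 had 1.03 without the doubted controls (adjusted p = 0.0607). Without them CDK16 and LBH passed, LBH at 0.77 (adjusted p = 0.0014). Ribosomal protein genes were higher as a group, with a median of 0.08 and adjusted p = 0.0032 (adjusted p = 0.894 with an estimated correlation). Nuclear oxidative phosphorylation genes were also higher (median 0.04, adjusted p = 0.0323; adjusted p = 0.894 with an estimated correlation). Unfolded protein response genes were lower (median -0.04, adjusted p = 0.0244; adjusted p = 0.170 with an estimated correlation), with 0 of 26 members called over all genes and 2 adjusted over the list alone, HSPA5, the ER chaperone BiP, at -0.24 (SE 0.06) and CRELD2 at -0.27 (SE 0.07). Adjusted p without the doubted controls was 0.208 for ribosomal proteins, 0.576 for oxidative phosphorylation and 0.0014 for the unfolded protein response (0.119 with an estimated correlation).

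The CDK18 knockout was compared in the same way. No gene passed on any day, nor over the mean of days. At an unadjusted p under 0.05 there were 1187, 2241 and 1059 genes at days 2, 4 and 6 and 1333 over the mean of days. DESeq2 called 3, 0 and 0 genes on those days and 0 over the mean, and limma with quality weights 0 in each. With both doubted controls left out edgeR called 0 on each day and over the mean, with 1728, 896, 920 and 878 at an unadjusted p under 0.05. The smallest p over the mean of days belonged to ZNF346 (log2 fold change -0.50, SE 0.10), APOL2 (0.55, SE 0.12) and CCDC149 (-0.88, SE 0.20), at adjusted p of 0.509, 0.509 and 0.526. Without control day 4 replicate 2, 1949 genes passed at day 4. In simulated counts for this comparison over the mean of days, 83.6% of genes changed 2-fold were recovered, and 47.8% of genes changed 1.5-fold. That simulation gave 154 calls, and many changed genes ease the adjusted threshold. Its shares can therefore overstate the recovery if few genes changed, and they do not show that such changes are absent.

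Mitochondrially encoded genes were higher as a group in CDK18 KO over the mean of days (median 0.17, adjusted p = 0.0054; adjusted p = 0.894 with an estimated correlation), with 0 of 13 called over all genes and 0 adjusted over the list alone. MT-CO2, a subunit of complex IV, had 0.52 (SE 0.17), MT-CYB 0.24 (SE 0.11) and MT-ND3 0.17 (SE 0.08). The mitochondrial share of gene counts in CDK18 KO (n = 2) was 9.65 ± 0.247% at day 2, 10.5 ± 1.71% at day 4 and 11.1 ± 0.189% at day 6. In control (n = 3) it was 9.98 ± 0.181%, 8.68 ± 0.482% and 9.51 ± 0.868%, so CDK18 KO was lower at day 2. The list's adjusted p without the doubted controls was 9.93e-05 (0.373 with an estimated correlation). Ribosomal protein genes (median 0.08, adjusted p = 0.0388) and nuclear oxidative phosphorylation genes (median 0.08, adjusted p = 0.0431) were higher too, each at adjusted p = 0.894 with an estimated correlation, and at 0.502 and 0.544 without the doubted controls.

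In the double knockout at day 6, 6 genes passed against control, 5 higher and 1 lower. DESeq2 called 13 higher and 12 lower, limma with quality weights 89 and 102, and edgeR with no filter 36 and 34, so the excess of higher genes depends on the method. The count of 6 became 3 without control day 6 replicate 1 or 3 or CDK16/18 dKO day 6 replicate 2, and 10 without control day 4 replicate 3. CORO1B (ENSG00000172725, chromosome 11, 67435510 to 67443821), which codes for an actin-binding coronin, rose to 45.8 ± 16.7 CPM from 5.69 ± 2.25 (log2 fold change 3.00, SE 0.28, adjusted p = 4.56e-08, n = 3 each). HCFC1R1 rose to 232 ± 36.9 CPM from 68.6 ± 16.6 (1.76, SE 0.31, adjusted p = 0.0283) and MMP2, a secreted gelatinase, to 18.0 ± 0.565 from 7.53 ± 1.43 (1.25, SE 0.25, adjusted p = 0.0457). RPL29 (ENSG00000162244, chromosome 3, 51993522 to 51995942), a ribosomal protein gene, rose to 395 ± 19.9 CPM from 202 ± 11.2 (0.97, SE 0.11, adjusted p = 1.19e-06), and BSG, which codes for basigin, by 1.25 (SE 0.22, adjusted p = 0.0091); both were chosen after their values were seen. The CDK16/18 dKO libraries of day 6 held 59.3, 59.2 and 25.5 CPM of BSG. The lowest of them lay below the highest single-knockout library of that day, at 26.7 CPM, and near the highest control, at 23.3 CPM. CDK16 was the gene that fell, by 1.23 (SE 0.19, adjusted p = 0.0016). Without the doubted controls CORO1B, RPL29, MMP2 and CDK16 passed, and HCFC1R1 and BSG had adjusted p of 0.201 and 0.1001 at log2 fold changes of 1.59 and 1.15, near those with all libraries. The MMP2 call was lost in 21 of 40 alternatives, with log2 fold changes of 1.14 to 1.41, the HCFC1R1 call in 12 and the BSG call in 6.

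**Figure D3:**
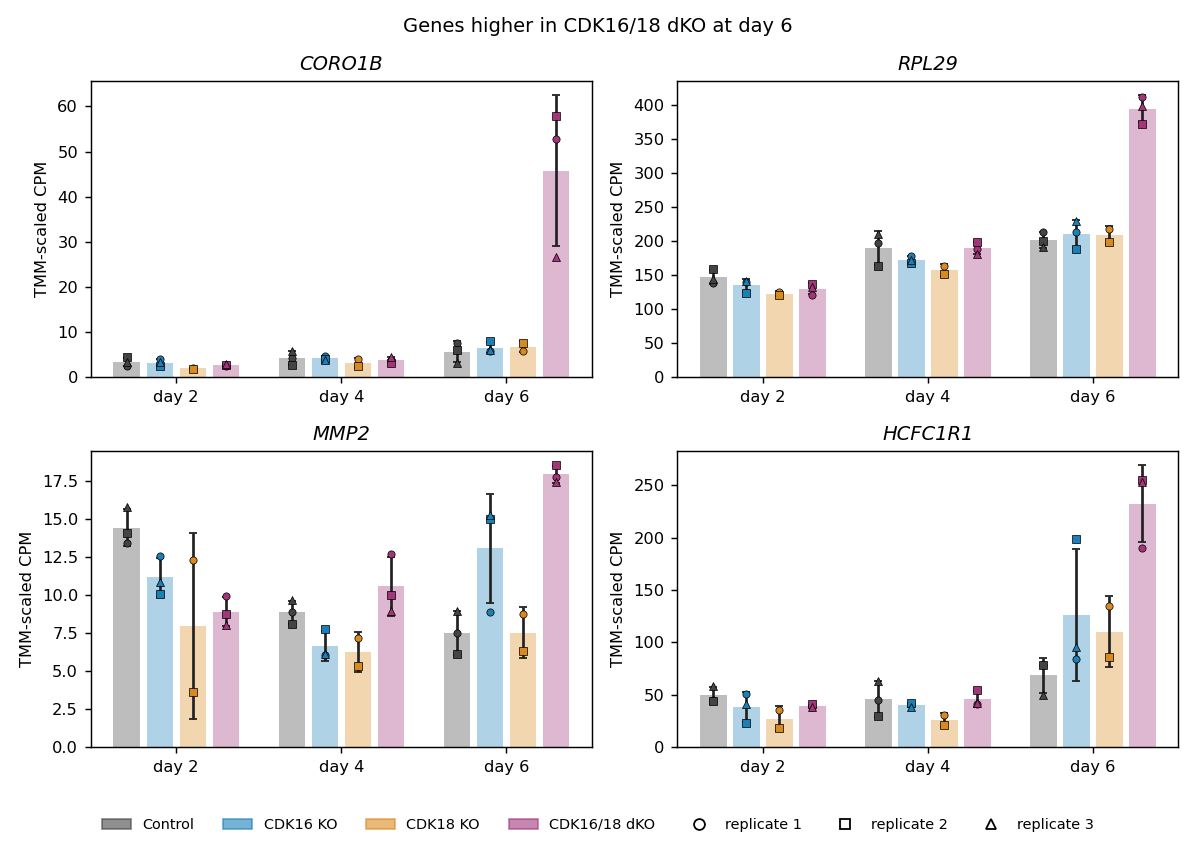
TMM-scaled CPM of CORO1B, RPL29, MMP2 and HCFC1R1 by labelled day and genotype. Bars are group means, error bars are the SD, and symbols are single libraries. At day 6 the lowest CDK16/18 dKO library stood above the highest single-knockout library for CORO1B (26.6 against 7.97 CPM), RPL29 (373 against 229 CPM) and MMP2 (17.5 against 15.3 CPM), and below it for HCFC1R1 (189.7 against 199 CPM). Tested against the single knockouts of day 6, CORO1B and RPL29 passed (adjusted p = 3.51e-09 and 2.24e-07), while MMP2 (0.114), HCFC1R1 (0.148) and BSG (0.0534) did not.

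G1/S and replication genes were lower as a group in CDK16/18 dKO at day 6, with a median of -0.18 over 47 members (adjusted p = 1.23e-07; adjusted p = 0.0016 with an estimated correlation). None was called over all genes and 3 were adjusted over the list alone, CCNE1, the gene of cyclin E1, at -0.49 (SE 0.11), GINS4, of the replicative helicase, at -0.51 (SE 0.12), and RRM2, of ribonucleotide reductase, at -0.47 (SE 0.13). Without the doubted controls the median was -0.17, with adjusted p = 0.0051 with an estimated correlation. G2/M genes had a median of -0.10 (adjusted p = 0.0262; adjusted p = 0.356 with an estimated correlation) and -0.06 without the doubted controls (adjusted p = 0.208). Unfolded protein response genes were lower (median -0.12, adjusted p = 0.0055; adjusted p = 0.0494 with an estimated correlation, and 0.295 so without the doubted controls), HSPA5 at -0.30 (SE 0.11) and HYOU1 at -0.32 (SE 0.12). On a day axis from the single knockouts these libraries of the double knockout stood at 0.785 to 0.872. The kept controls stood at 0.920 and 0.930 on the axis of all knockouts, which has other genes and another scale. The place of the double knockout was not separated from the genotype for any list at this day. Camera at the preset correlation called 9 lists at this day, and these G1/S and unfolded protein response lists were the 2 that passed with an estimated correlation.

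At day 4 unfolded protein response genes were also lower in CDK16/18 dKO (median -0.12, adjusted p = 0.0037; adjusted p = 0.0345 with an estimated correlation, and 0.0369 so without the doubted controls), with 0 of 26 called over all genes and 2 adjusted over the list alone. The double knockout libraries of day 4 stood at 0.077 to 0.170 on a day axis from the single knockouts. The kept controls of day 4 stood at 0.015 and -0.029 on the axis of all knockouts. The place of the double knockout was not separated from the genotype at day 4 either. At days 2 and 4 no gene passed in CDK16/18 dKO with edgeR, with 571 and 1551 at an unadjusted p under 0.05. DESeq2 called 0 and 48, and limma with quality weights 0 and 1. With a fit on the compared groups alone 477 passed at day 2. The smallest p at day 4 belonged to FUT1 (-2.66, SE 0.49, adjusted p = 0.0679), CCDC34 (0.76, SE 0.14, adjusted p = 0.0679) and PDLIM4 (-0.71, SE 0.15, adjusted p = 0.192). At day 2 it belonged to KRT75 (-2.07), ZNF653 (-1.72) and PMEPA1 (-0.61). Without control day 4 replicate 2, 811 genes passed at day 4. Over the mean of days CDK16 was the 1 called gene, as it was without the doubted controls (log2 fold change -0.69, adjusted p = 0.0403), and unfolded protein response genes were lower (median -0.04, adjusted p = 0.0323; adjusted p = 0.170 with an estimated correlation).

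Nucleoporin and DNA repair genes, the groups named by the series title, did not pass as lists in any knockout over the mean of days. On single days none of them passed with an estimated correlation: 0 lists did so in CDK16 KO or CDK18 KO. In CDK16/18 dKO the 1 list at day 4 and the 2 at day 6 that did were those named above. At the preset correlation camera called 10 lists in CDK16 KO and 7 in CDK18 KO at day 6, and 10 in CDK16/18 dKO at day 4. Whether pore or repair lists were among those is not given here. In CDK16/18 dKO the 32 nucleoporins had a median of 0.04 (adjusted p = 0.532), with NUP42 at 0.25 (SE 0.12) and NUP37 at 0.27 (SE 0.16) among the smallest p. Homologous recombination genes had a median of 0.04 (adjusted p = 0.229), with MUS81, a structure-specific nuclease, at 0.27 (SE 0.14) and RAD51AP1 at 0.24 (SE 0.13). Medians were 0.01 for the Fanconi anaemia pathway (adjusted p = 0.852), -0.07 for end joining (0.756), 0.04 for excision and mismatch repair (0.613), 0.02 for DNA damage signalling (0.738) and 0.03 for nuclear transport factors (0.463). None of their members was called over all genes or adjusted over the list alone. The test says nothing of protein or of repair itself, and a median near 0 over members of both signs leaves single members open.

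The double knockout was also set against each single one over the mean of days. RPL29 (log2 fold change 0.42, SE 0.07, adjusted p = 0.0099) and CORO1B (1.15, SE 0.21, adjusted p = 0.0403) were higher than in CDK18 KO, both chosen after their values were seen. The RPL29 call was lost in 3 of 40 alternatives, each without a CDK18 KO library numbered 2, and the CORO1B call in 20. Against CDK16 KO no gene passed with edgeR, with 569 at an unadjusted p under 0.05; DESeq2 called 1 and limma with quality weights 10. RPL29 (0.33, SE 0.06, adjusted p = 0.0900), CORO1B (0.81, SE 0.18, adjusted p = 0.631) and RPS6KA4 (0.37, SE 0.09) had the smallest p there. Without the doubted controls 4 passed, LBH, RPL29, LOXL4 and CORO1B, with RPL29 at adjusted p = 0.0084.

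Whether a knockout's effect changed from day 2 to day 6 was tested as an interaction. In CDK16/18 dKO 5 genes passed, all with an effect more positive at day 6, and the same 5 passed without the doubted controls. DESeq2 called 9 more positive and 5 more negative, limma with quality weights 31 and 37, and edgeR with no filter 27 and 24. Without control day 2 replicate 2, or CDK16/18 dKO day 2 replicate 3, 2 passed, and without control day 2 replicate 3, control day 6 replicate 1 or CDK16/18 dKO day 6 replicate 2, 3 passed. The calls of MMP2, PMEPA1 and KRT75 were lost in 7, 8 and 3 of 40 alternatives, and those of CORO1B and RPL29 in 0. The 5 were CORO1B (difference 3.33 on the log2 scale, SE 0.43, adjusted p = 6.49e-05), RPL29 (1.15, SE 0.15, adjusted p = 6.49e-05), MMP2 (1.95, SE 0.35, adjusted p = 0.0142) and, chosen after their values were seen, KRT75, a keratin, (3.70, SE 0.63, adjusted p = 0.0082) and PMEPA1, a TGF-beta-induced gene, (1.13, SE 0.21, adjusted p = 0.0142). KRT75 averaged under 5 CPM over all libraries, so its large difference rests on low counts. The effect on G1/S and replication genes was more negative at day 6 (median difference -0.23, adjusted p = 1.54e-05; adjusted p = 0.0091 with an estimated correlation, and 0.0154 so without the doubted controls). No gene passed in CDK16 KO or CDK18 KO with edgeR, with 958 and 1360 at an unadjusted p under 0.05. DESeq2 called 1 and 0 there, and limma with quality weights 1 and 0. PMEPA1 had the smallest p in CDK16 KO (1.10, SE 0.21, adjusted p = 0.108) and KRT75 in CDK18 KO (3.91, SE 0.78, adjusted p = 0.276).

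Fold changes of the knockouts against control were correlated across the 16103 genes, which are not independent replicates. Over the mean of days r was 0.496 between CDK16 KO and CDK18 KO, 0.578 between CDK16 KO and CDK16/18 dKO, and 0.569 between CDK18 KO and CDK16/18 dKO. Unchanged groups simulated against the same controls gave 0.434, 0.501 and 0.434. The covariances were 0.0307, 0.0305 and 0.0371 against simulated values of 0.0235, 0.0234 and 0.0234. Simulated libraries were drawn independently for each gene, with a spread estimated with the doubted controls in. Their values need not match those of unchanged real groups, so the gaps cannot decide whether effects are shared. With a different control replicate number for each knockout, r averaged 0.106, 0.111 and 0.136, and the covariance 0.0157, 0.0155 and 0.0206. With control numbers 1 and 2 alone, which leaves out the doubted libraries, r averaged 0.044, 0.068 and 0.068. The covariance there averaged 0.0060, 0.0087 and 0.0093. Each such response rests on 1 control library a day, which adds noise and lowers r. These r values therefore cannot be set against those with shared controls.

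In control cells 953 genes rose and 1031 fell from day 2 to day 6, and 1774 rose and 1647 fell without the doubted libraries. Without control day 6 replicate 2 the total was 1013, against 1984 with all libraries. GDF15, a stress-induced cytokine, rose to 94.2 ± 60.4 CPM from 4.55 ± 1.09 (log2 fold change 4.37, SE 0.62, adjusted p = 8.88e-05, n = 3 each), LINC00520 by 3.85 (SE 0.55) and IFIT3, an interferon-induced gene, by 3.01 (SE 0.61, adjusted p = 0.0023). C5orf46 fell by 2.14 (SE 0.21), COL3A1, a fibrillar collagen, by 2.03 (SE 0.31) and TET1, a DNA demethylase, by 1.99 (SE 0.22). Without the doubted libraries GDF15 rose by 4.82 (adjusted p = 3.40e-15, 128 CPM at day 6), LINC00520 by 4.29 and IFIT3 by 3.50, and C5orf46 fell by 2.35, COL3A1 by 1.79 and TET1 by 1.95.

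Amino acid and endoplasmic reticulum stress genes were higher as groups at day 6 in control cells, with part of each list called. Of 35 ATF4 response genes 25 rose over all genes and 27 adjusted over the list alone (median 0.74, adjusted p = 8.71e-18; adjusted p = 0.0025 with an estimated correlation), with ASNS, asparagine synthetase, at 1.503 (SE 0.20) and NUPR1 at 1.46 (SE 0.17). Of 26 unfolded protein response genes 12 rose, and 20 adjusted over the list alone (adjusted p = 3.21e-06 with an estimated correlation), HERPUD1 by 1.94 (SE 0.18) and XBP1 by 0.74 (SE 0.13). Of 27 p53 target genes 15 rose, and 18 adjusted over the list alone (adjusted p = 1.92e-06 with an estimated correlation), CDKN1A, which codes for p21, by 1.07 (SE 0.12). Autophagy and lysosome genes were higher (9 rose and 1 fell of 31, 11 and 1 adjusted over the list alone; adjusted p = 0.0061 with an estimated correlation), as were NF-kB and acute-phase genes (7 of 16 rose, and 7 adjusted over the list alone; adjusted p = 0.0079 with an estimated correlation), CXCL8 by 2.70 (SE 0.63).

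Cell division genes were lower as groups, though most members of each list were not called over all genes. Of 46 G2/M genes 21 fell, and 26 adjusted over the list alone (median -0.38; adjusted p = 0.0013 with an estimated correlation), CENPF by 1.36 (SE 0.20) and TOP2A by 1.01 (SE 0.18). Of 47 G1/S and replication genes 8 fell, and 14 adjusted over the list alone (adjusted p = 0.0061 with an estimated correlation), ATAD2 by 0.93 (SE 0.16). Of 31 homologous recombination genes 1 rose and 9 fell, 2 and 13 adjusted over the list alone (adjusted p = 1.05e-04; adjusted p = 0.118 with an estimated correlation), BRCA2 by 1.85 (SE 0.30) and BRCA1 by 0.87 (SE 0.17). End joining (4 of 19 fell, 6 adjusted over the list alone; adjusted p = 0.0491 with an estimated correlation), DNA damage signalling (5 of 21 fell, 6 adjusted over the list alone; 0.0677 so estimated) and the Fanconi anaemia pathway (4 of 19 fell, 4 adjusted over the list alone; 0.0774 so estimated) were lower. Excision and mismatch repair did not pass (2 of 31 fell, 2 adjusted over the list alone; adjusted p = 0.211). Of 32 nucleoporins 3 fell, and 3 adjusted over the list alone (adjusted p = 0.0286; adjusted p = 0.397 with an estimated correlation), TPR by 1.12 (SE 0.19) and RANBP2 by 0.99 (SE 0.20), and of 31 nuclear transport factors 5 fell, and 6 adjusted over the list alone (adjusted p = 0.0019; adjusted p = 0.131 with an estimated correlation).

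Interferon-stimulated genes were higher (10 rose and 1 fell of 38, 17 and 1 adjusted over the list alone; adjusted p = 6.44e-05; adjusted p = 0.112 with an estimated correlation), OASL by 4.79 (SE 0.96). Ribosomal protein genes were higher (23 of 78 rose, 44 adjusted over the list alone; adjusted p = 0.105 with an estimated correlation), as were nuclear oxidative phosphorylation genes (4 rose and 1 fell of 59; adjusted p = 0.398 with an estimated correlation), glycolysis and hypoxia genes (6 of 31 rose, 7 adjusted over the list alone; adjusted p = 0.131 with an estimated correlation) and cholesterol synthesis genes (1 of 24 rose, 0 adjusted over the list alone; adjusted p = 0.518 with an estimated correlation). Mesenchymal and adhesion genes were lower (3 rose and 7 fell of 28, 5 and 11 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation), TPM1 by 1.13 (SE 0.13), while ACTA2 rose by 2.26 (SE 0.29). Fibroblast-like markers were lower (5 of 7 fell, and 5 adjusted over the list alone, adjusted p = 2.25e-04 with an estimated correlation), COL1A1 by 1.19 (SE 0.18). Of the 10 markers in that list, 5 reached a mean of 5 CPM in these cells. The lists of fatty acid synthesis (adjusted p = 0.733), YAP/TEAD target genes (0.645), the heat shock response (0.259), mitochondrially encoded genes (0.120), hepatocyte transcription factors (0.595), hepatocyte plasma proteins (0.949), HEK293T-like (0.789) and blood-cell markers (0.992) and the TAIRE kinases with cyclin Y (0.528) did not pass. HEK293T-like and blood-cell markers had positive medians, 0.09 and 0.39, while their test pointed down. Adjusted over the list alone, 2 rose and 2 fell of 20 fatty acid genes, 5 and 5 of 22 YAP/TEAD genes, and 3 and 2 of 9 hepatocyte transcription factors.

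Without the doubted libraries some of these lists in control cells changed their result with an estimated correlation. Nucleoporins were lower (1 rose and 8 fell, adjusted p = 0.0154), as were nuclear transport factors (11 fell, adjusted p = 6.17e-04), heat shock genes (9 fell, adjusted p = 0.0014) and mesenchymal and adhesion genes (3 rose and 13 fell, adjusted p = 0.0083). Interferon-stimulated genes (21 rose and 1 fell, adjusted p = 1.85e-05), cholesterol synthesis (14 rose, adjusted p = 6.49e-04), glycolysis and hypoxia genes (10 rose, adjusted p = 0.0120) and fatty acid synthesis (6 rose and 1 fell, adjusted p = 0.0414) were higher. End joining had an adjusted p of 0.0711 so estimated. The ATF4 response (29 rose and 1 fell), p53 target genes (18 rose), the unfolded protein response (14 rose), G1/S and replication genes (1 rose and 15 fell), G2/M genes (25 fell), NF-kB and acute-phase genes (6 rose), autophagy and lysosome genes (13 rose and 1 fell) and fibroblast-like markers (5 fell) passed with and without those libraries.

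**Figure D4:**
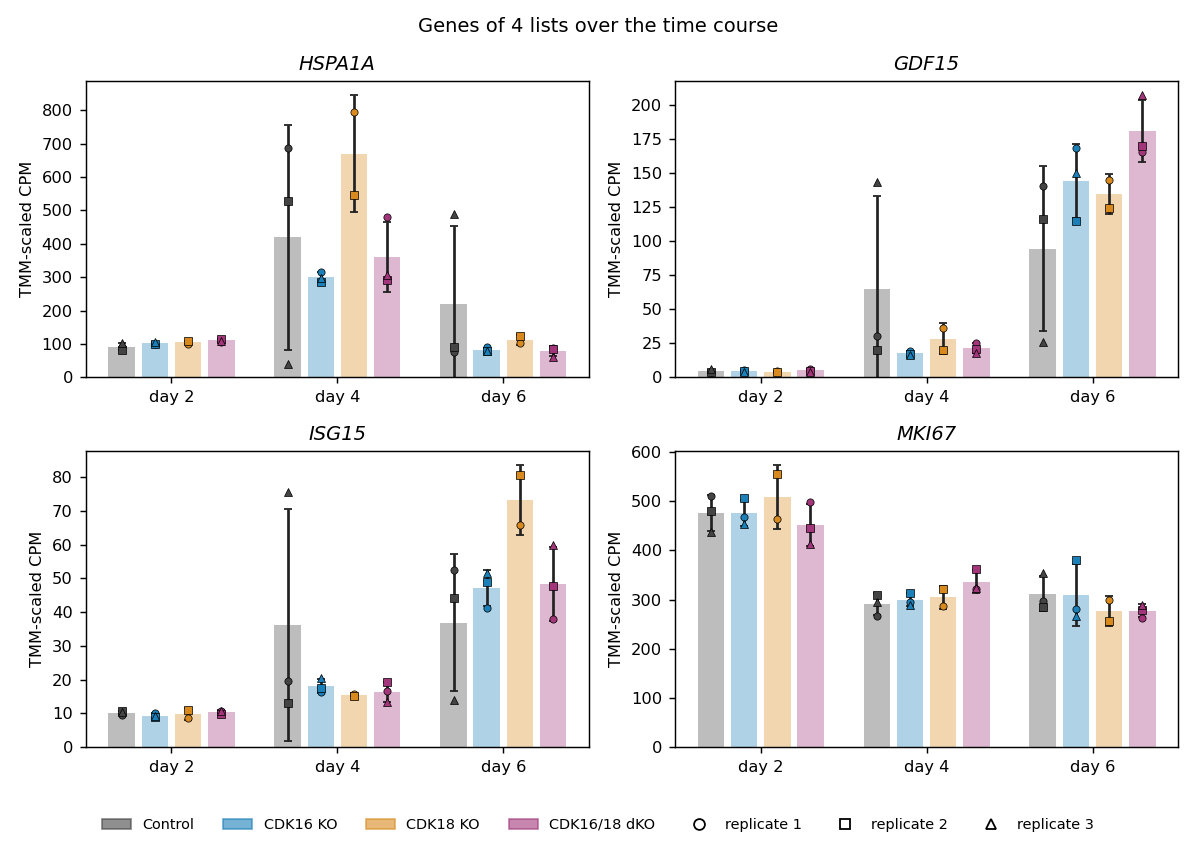
TMM-scaled CPM of HSPA1A, GDF15, ISG15 and MKI67 by labelled day and genotype, genes chosen after their values were seen. Bars are group means, error bars are the SD (lower ends below 0 are not drawn), and symbols are single libraries. The control libraries numbered 3 at days 4 and 6 lie apart from the others of their label for HSPA1A, GDF15 and ISG15.

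Genes of hepatocyte plasma proteins were near the floor in every library. Of 41 hepatocyte plasma protein genes 35 had at least 1 count somewhere, 5 reached a mean of 1 CPM and 0 reached 5 CPM. ALB, the gene of serum albumin, had 0 counts in the 33 libraries. RBP4 had the highest mean, 2.34 ± 0.829 CPM (SD, n = 33), followed by AFP, alpha-fetoprotein, at 1.93 ± 0.745 and SERPINA1, alpha-1-antitrypsin, at 1.87 ± 0.698. The list held 0.0011% to 0.0019% of gene counts in a library. Of 21 hepatocyte transcription factors 6 reached a mean of 5 CPM. HNF4A, a hepatocyte transcription factor, stood at 0.0772 ± 0.123 CPM, while FOXA2 stood at 19.8 ± 4.64 and RXRA at 70.1 ± 12.9. VIM, the mesenchymal filament vimentin, stood at 1222 ± 99.0 CPM, COL1A1 at 402 ± 166, SPARC at 335 ± 51.6 and KRT18, an epithelial keratin, at 453 ± 102.

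**Figure D5:**
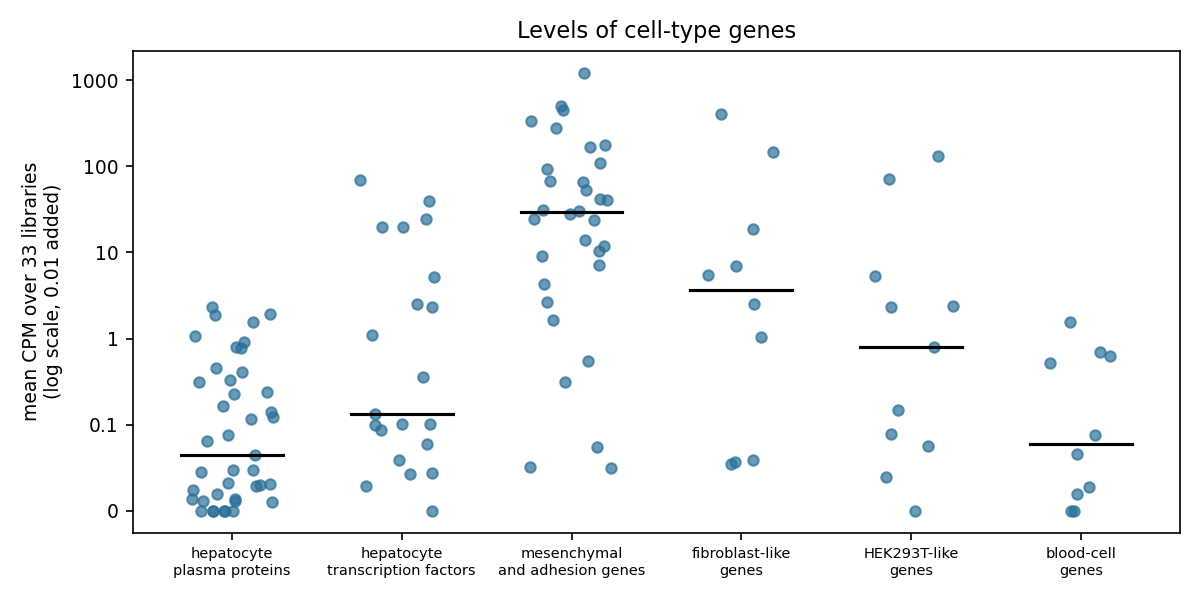
Mean CPM over the 33 libraries (log scale, 0.01 added) of each member of 6 marker lists; each point is a gene and each bar is the list's median. Hepatocyte plasma protein genes reach at most 2.34 CPM, against 1222 CPM for the highest mesenchymal and adhesion gene.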

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

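Tests of the day labels, of cell identity and of CORO1B and RPL29 were chosen after the results were seen, as were the fit without a pair of control libraries and the time comparisons of the knockouts; the expected outcomes of the splits were also written down after they had been run.

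The effect of the double knockout differed between days 2 and 6, by the test of the difference itself (edgeR quasi-likelihood, Benjamini-Hochberg), for 5 genes. CORO1B had a difference of 3.325 on the log2 scale, KRT75 3.703, MMP2 1.951, RPL29 1.146 and PMEPA1 1.128. Without control day 2 replicate 2, or CDK16/18 dKO day 2 replicate 3, 2 genes passed. The single knockouts, set against the same controls, had differences of like size that did not pass, 3.91 for KRT75 in CDK18 KO and 1.10 for PMEPA1 in CDK16 KO, so these are not shown to be the double knockout's own. At day 2 KRT75 and PMEPA1 had log2 fold changes of -2.07 and -0.61, neither past the threshold. KRT75 averaged under 5 CPM over all libraries, so its fold changes rest on low counts. As a mean of days the double knockout differed from CDK18 KO for RPL29 (0.424) and CORO1B (1.155). The latter call was lost in 20 of 40 alternatives. CORO1B stood at 45.8 CPM in the double knockout at day 6, against at most 7.97 CPM in a single-knockout library of that day.

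The first pattern is that the control libraries numbered 3 at days 4 and 6 sit with the other day, at places 0.996 and 0.027. A mixture of RNA from both days in each library would bring the places together, and they are 0.970 apart. Low depth is argued against by 7.65 M gene counts in the shallower of the pair, within the range of the other libraries. A library of a CDK16-targeted group under the control day 4 label is argued against by 163.2 CPM of CDK16, above the 45.3 to 77.2 CPM of those libraries at day 6. A CDK18 KO library of day 6 under the control day 4 label was not tested, and those libraries held 186 and 121 CPM of CDK16. Exchanged day labels are a candidate explanation, and a library of another experiment was not tested.

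The second pattern is that hepatocyte plasma protein genes are near the floor. Genes missing from the counting are argued against by 35 of 41 members with at least 1 count. Loss after the knockouts is argued against by the control libraries, where the list held at most 0.0017% of gene counts. With 0 members at a mean of 10 CPM, and VIM at 1222 CPM, cells that do not make hepatocyte proteins under the Huh7 label may be the source. Whether these are another line or Huh7 cells changed in culture was not tested, and no biological explanation was tested.

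The third pattern is the gain of CORO1B and RPL29 in CDK16/18 dKO at day 6. The doubted day 6 control is argued against as the whole cause, since against the single knockouts of day 6 the smaller of both log2 fold changes was 0.913 (RPL29, SE 0.09; CORO1B 2.78, SE 0.23). More copies of the regions is argued against by the 44 genes within 500 kb, with a median of -0.060 (SD 0.29). RPL29 pseudogenes held 1.541 CPM together in the other day 6 libraries, but reads with more than 1 alignment were dropped, so a shift of such reads into RPL29 would not show there and stays open. An effect of losing both kinases, of the viruses used or of a single infection stays open, since the 3 libraries may share 1 infection.

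Other splits of the same libraries were set beside the real one, but too few were drawn to exclude chance. The smallest share that 22 splits can give is 0.0455, and no adjustment was made over the comparisons. With 22 splits, the real one included, the real split alone gave as many genes for CDK16 KO over the mean of days (1 of 22 splits; 2 genes, highest other 0), CDK16/18 dKO against CDK18 KO (1 of 22; 2 genes, highest other 0), the day 2 to day 6 change of the dKO effect (1 of 22; 5 genes, highest other 2), and the knockouts at day 4 against day 2 (1 of 22; 3897, highest other 0) and day 6 against day 2 (1 of 22; 7090, highest other 2261). For CDK16/18 dKO over the mean of days other splits gave as many genes (3 of 22 splits, 1 gene, highest other 2). Where the real count was 0, each split has at least as many, so the splits say nothing of chance: CDK18 KO over the mean of days (22 of 22, highest other 1262), CDK16/18 dKO against CDK16 KO (22 of 22, highest other 0) and the CDK16 KO change with time (22 of 22, highest other 0). What gave the 1262 genes of a CDK18 split was not tested.

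With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 0 and 0 for CDK16 KO at day 2 (10 of 10 splits as large), 10 and 0 at day 4 (1 of 10) and 3 and 0 at day 6 (1 of 10). They were 0 and 0 for CDK16/18 dKO at day 2 (10 of 10), 0 and 157 at day 4 (10 of 10), 6 and 12 at day 6 (2 of 10), and 1984 and 1 for control at day 6 against day 2 (1 of 10). The 157 genes of a day 4 split and the 12 of a day 6 split exceed the real counts, and what gave them was not tested.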

How the results depend on the processing

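The fit without the control libraries numbered 3 at days 4 and 6 was chosen after the data were examined, as were the time comparisons of the knockouts; the other alternatives were not. Among counts, correlations and called lists, 855 alternative values stayed within 1.5 times the value reported, or within its spread, and 173 moved. For the called genes named and for CDK16 and CDK18 over the mean of days, 1872 alternative values stayed on their side of the threshold, 168 lost the call and 0 reversed. A change of sign counted as reversed only for a gene called in the reported or the alternative fit. CDK18 in CDK16 KO, called in neither, ran from -0.187 to 0.134 on the log2 scale. Genes named with the smallest p, list members and genes that gained a call without the doubted controls, such as HSPA1A, LBH and ARHGDIB, are not in these numbers. CORO1B, RPL29 and CDK16 at day 6 in CDK16/18 dKO, and CDK16 over the mean of days in both CDK16-targeted genotypes, passed in all 40 alternatives. MMP2 at day 6 lost its call in 21 of 40, HCFC1R1 in 12, RPL13AP20 in 13, L1CAM in 11, ACKR3 over the mean of days in 15, CORO1B against CDK18 KO in 20, SMAD6 in 4 and SOX9 in 4. Most of the 40 alternatives leave out a single library, often one outside the groups compared. Such counts, and the 1872 above, include many fits that kept every compared library, so they can overstate how firm a call is. SMAD6 and SOX9 lost their calls without control day 4 replicate 1, or CDK16 KO day 4 replicate 2 or 3. Those libraries are in the compared groups, and a fit on these groups alone lost both calls too. Where no cause is named below, the cause was not tested.

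With size factors of the RLE type, 1 list was called in CDK18 KO over the mean of days in place of 3. Without the expression filter more genes with few counts are tested, and counts rose to 172 and 79 in CDK16 KO at days 4 and 6, 99, 414 and 28 in CDK18 KO at days 2, 4 and 6, and 29, 192 and 70 in CDK16/18 dKO. As a mean of days they rose to 19, 150 and 62 in CDK16 KO, CDK18 KO and CDK16/18 dKO. They were 23 for the double knockout against CDK16 KO, 7 against CDK18 KO, and 52, 84 and 51 for the change of the CDK16, CDK18 and double knockout effects with time. The correlations of CDK16 KO and CDK18 KO with CDK16/18 dKO were 0.508 and 0.467, and 1 list was called in each of CDK18 KO and CDK16/18 dKO.

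With the replicate number as a block, 2 genes were called in CDK16/18 dKO over the mean of days and 1 list in that comparison. With the block MMP2 and HCFC1R1 at day 6 in CDK16/18 dKO lost their calls (adjusted p = 0.0771 and 0.0713), as did RPL13AP20 at day 6 (0.0517) and ZBTB47 and PDLIM4 at day 4 (0.0815 and 0.0581) in CDK16 KO, at log2 fold changes of 1.26, 1.78, -0.81, -1.60 and -0.78. Pairs of libraries with the same number and day had residual correlations of -0.255 to 0.260, and 8 of 45 were over 0.1, so the numbers gave little sign of a pairing. Numbers follow the sample titles, and for CDK18 KO at days 4 and 6 the letters of the deposited files differ from them, so the block and this check may pair those libraries wrongly. With a fit on the compared groups alone, which has fewer libraries to estimate the spread, 2 genes were called in CDK16 KO at day 2, 0 at day 4, 0 at day 6, 3 in CDK18 KO at day 2, 477 in CDK16/18 dKO at day 2, 2 against CDK16 KO, 1 against CDK18 KO, and 1 for the CDK16 KO change with time.

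With limma and quality weights, counts were 98 and 5 in CDK16 KO at days 4 and 6, 1 and 191 in CDK16/18 dKO at days 4 and 6, 1 and 57 over the mean of days in CDK16 KO and CDK16/18 dKO, 10 against CDK16 KO, 4 against CDK18 KO, 1 and 68 for the change of the CDK16 KO and CDK16/18 dKO effects with time, and 4603 for control at day 6 against day 2. With DESeq2 they were 36 and 6 in CDK16 KO at days 4 and 6, 3 in CDK18 KO at day 2, 48 and 25 in CDK16/18 dKO at days 4 and 6, 1 against CDK16 KO, and 1 and 14 for the CDK16 KO and CDK16/18 dKO changes with time. With an estimated correlation 0 lists were called over the mean of days in CDK16 KO, 0 in CDK18 KO and 0 in CDK16/18 dKO.

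Without both doubted controls, 67 genes were called in CDK16 KO at day 4, 4 for the double knockout against CDK16 KO, 3421 for control at day 6 against day 2 and 1 list in CDK16/18 dKO. The common coefficient of variation was 0.131 in place of 0.160.

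Leaving out each of the 33 libraries in turn, counts ran from 0 to 0 in CDK16 KO at day 2, from 2 (without CDK16 KO day 4 replicate 3) to 1113 (without control day 4 replicate 2) at day 4 and from 0 (without control day 6 replicate 1) to 7 (without control day 4 replicate 3) at day 6. In CDK18 KO they ran from 0 to 26 (without CDK18 KO day 2 replicate 1), 0 to 1949 (without control day 4 replicate 2) and 0 to 1 (without control day 6 replicate 1). In CDK16/18 dKO they ran from 0 to 0, 0 to 811 (without control day 4 replicate 2) and 3 (without control day 6 replicate 1) to 10 (without control day 4 replicate 3). Without control day 4 replicate 2 the day 4 controls left are the doubted library and replicate 1. For the mean of days the ranges were 1 to 2 in CDK16 KO, 0 to 0 in CDK18 KO and 1 to 28 (without control day 4 replicate 2) in CDK16/18 dKO, 0 to 1 against CDK16 KO and 0 (without CDK18 KO day 2 replicate 2) to 2 against CDK18 KO. For changes with time they were 0 to 1, 0 to 1 and 2 (without control day 2 replicate 2) to 7 (without control day 2 replicate 1). Control at day 6 against day 2 ran from 1013 (without control day 6 replicate 2) to 2688 (without control day 6 replicate 3), and the knockouts from 2772 to 4493 at day 4 and 6152 to 7550 at day 6. The correlations ran from 0.434 to 0.623 for CDK16 KO with CDK18 KO, 0.525 to 0.692 for CDK16 KO with CDK16/18 dKO and 0.488 to 0.683 for CDK18 KO with CDK16/18 dKO, the highest each without control day 4 replicate 2. Called lists ran from 0 to 7, 0 to 5 and 0 to 4. Where CDK18 KO was left with 1 library at a day, that library was taken to vary like the other groups.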

Other observations

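The comparisons of days among the knockout genotypes and the genes named in them were chosen after the data were examined, and no hypothesis is offered for them. In the 8 knockout libraries of each day, 1849 genes rose and 2048 fell from day 2 to day 4, and 3504 rose and 3586 fell from day 2 to day 6 (edgeR quasi-likelihood, Benjamini-Hochberg). At day 4 counts of the 7SK RNA rose by 3.56 on the log2 scale (SE 0.36), ESM1 by 3.55 (SE 0.42) and SNORD46 by 3.33 (SE 0.43). CXCL14 fell by 2.19 (SE 0.36), SHOC1 by 2.06 (SE 0.17) and IGFBP5 by 2.01 (SE 0.47). The library kit primes on the poly(A) tail, and how reads of 7SK and SNORD46 arose was not tested. At day 6 GDF15 rose by 5.02 (SE 0.41), IFIT2 by 3.57 (SE 0.44) and LINC00520 by 3.56 (SE 0.33), while DIO2 fell by 2.80 (SE 0.17), ENSG00000258115 by 2.21 (SE 0.23) and C5orf46 by 2.11 (SE 0.13).

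Heat shock genes stood higher at day 4 than at day 2 in the knockouts, with 7 of 22 called over all genes and 8 adjusted over the list alone (adjusted p = 2.71e-04; adjusted p = 0.402 with an estimated correlation). HSPA1A rose by 1.98 (SE 0.40, adjusted p = 7.28e-04) at day 4 and had -0.23 at day 6 (adjusted p = 0.659). At day 6, 17 of 32 nucleoporins fell and 1 rose (adjusted p = 3.84e-04; adjusted p = 0.147 with an estimated correlation), TPR by 1.05 and RANBP2 by 1.08, and 24 of 38 interferon-stimulated genes rose and 1 fell (adjusted p = 0.0379 with an estimated correlation).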
